A study of Mus musculus with 1307 samples.

How the data were processed

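Single cells from enzymatically dissociated mouse hearts were sorted by FACS into 384-well plates and processed with Smart-Seq2, a full-length cDNA method without molecular identifiers, per the labels' protocols. The labels do not state the sort gate. Each cell is a sample of its own in the labels, which name its strain or reporter genotype, its mouse, its sex and its plate. The 4 groups were double-reporter mice (ACTA2GFP:CSPG4dsRED, 949 cells of 3 mice), C57BL/6 mice (352 cells of 3 mice), CSPG4dsRED mice (3 cells of 1 mouse) and ACTA2GFP mice (3 cells of 1 mouse). Each of the 4 mice with many cells was on 1 plate of its own, so that mouse and plate could not be separated. The mouse, not the cell, was the replicate throughout.

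The values used were the deposited counts, whole-number read counts per gene and cell as the authors made them. Per the submitters' processing notes, bcl2fastq, Bowtie, Bowtie2, Subread and featureCounts were used with the GRCm38 (mm10) build. Their versions, the order of the steps and the strand setting were not given in the sources used here. The table held 46517 genes, of which 46005 had a symbol and 16915 had no count in any cell. All 1307 cell columns matched 1 sample each by name, and no pair of cells held identical values. The 118 genes that shared a symbol with another gene were kept apart by their Ensembl identifier. Whether reads with the same position had been removed was not given in the sources used here. As a check, the highest count of each gene in any cell was divided by its exonic length in the GENCODE M21 annotation. The highest value was 2.00 counts per base, no gene exceeded 2 per base, and the median was 0.0763 over the 17089 genes with more than 50 counts in a cell. Acta2 reached 1.02 and Myl9 1.30 counts per base. Whether a ceiling on counts exists was left open.

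The cells held between 50476 and 811982 counts each (median 274702) and a median of 4549 detected genes. All 1307 passed the filter of at least 10000 counts and 500 genes. A stricter filter of 100000 counts and 2000 genes left 1219. Confidence intervals of shares are exact binomial (Clopper-Pearson) at 95%. The limit that a count of 0 allows was set at 3 counts. Because reads amplified by PCR are not independent molecules, all intervals and limits cover counting error only.

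Cells were normalised to 100000 counts and log-transformed with scanpy 1.11.5 (Python 3.11.15). The 2000 most variable genes, 30 principal components and 15 neighbours entered Leiden clustering (leidenalg 0.10.2) at resolution 1 with seed 0. Before that step 434 genes were withheld: the members of all fixed lists and markers, mitochondrial, rRNA-like and sex-linked genes. A cluster was named from 14 marker sets alone when at least 3 markers of a class reached 100 CPM (counts per 1000000) and 2 times their mean over clusters. Clusters with a near-equal second class, or with more markers of another class among their 10 leading genes, stayed unnamed. Doublets were called per mouse with Scrublet, which marked 2, 2, 3 and 0 cells of the 4 large mice. They stayed in, and leaving them out was an alternative. The classes are rebuilt here from expression and have no check against another measurement of cell identity.

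For each comparison between classes, raw counts were summed per mouse and class over at least 10 cells. In the subcluster tests a sum needed at least 4 cells, and the smallest sum in that of subcluster 0 held 8. The sums were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at 0.05) in R 4.3.3, with the mouse as a block because both classes came from the same animals. Over 5571 genes, the deviations of smooth muscle-like and fibroblast-like sums from their class means correlated within a mouse (r = 0.139, 0.311 and 0.181). The 13 gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01), with an estimated correlation as the alternative, and with fry, which tests whether the genes of a list move and not whether they move more than other genes. Naming markers of the smooth muscle, pericyte and fibroblast classes compared were left out of the list counts. Markers of mural cells of either kind and of other classes stayed in, except in the lists of subcluster 0, and leaving them out was an alternative added after seeing the data. Mean CPM values and SDs are over mice, on each mouse's summed counts. Comparisons between mice within a class used the same test without a block. Where fewer than 3 mice qualified for smooth muscle-like against endothelial-like or pericyte-like against fibroblast-like cells, values were given without a test, as planned.

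The text names genes by a fixed rule. Per comparison these are the 8 largest changes each way among called genes with the same direction in every mouse, an average log2 CPM of at least 5 and no use in naming. To these come up to 4 members per fixed list, naming markers of the compared classes aside: the 2 called members with the largest change each way, or, with none called, the 2 of lowest p. Genes that entered the clustering are given only as class-defining. Within a class, the rule takes the 5 largest changes each way, the sex-linked genes, Acta2 and Cspg4. The samples, tests, lists, markers, this rule and most alternatives were fixed before the data were examined. Several further tests were chosen after seeing the data: sums of at least 4 cells, either smooth muscle-like cluster alone, cells without high endothelial markers, the smaller subclusters, the unnamed cluster 4, the sexes in fibroblast-like cells, and the double-reporter against C57BL/6 comparison in Schwann-like cells.

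The edgeR tests were run on simulated data drawn from the real means and library sizes, with 100 genes changed by 2 and 100 by 4 on the log2 scale. For smooth muscle-like against pericyte-like cells (14392 genes) it recovered 5% of the smaller and 36% of the larger changes with 1 false call. For smooth muscle-like against fibroblast-like cells (15813 genes) it recovered 29% and 61% with 2 false calls. For pericyte-like against fibroblast-like cells with at least 4 cells (14797 genes) the shares were 3% and 25%. For subcluster 0 of the smooth muscle-like cells (11898 genes) they were 10% and 45%. For the female mouse against the males (16114 genes) they were 20% and 60% with 8 false calls, and for the strain comparison in Schwann-like cells (14214 genes) 3% and 28% with 7 false calls. For smooth muscle-like against pericyte-like cells with at least 4 cells (12882 genes) they were 7% and 35%, for subclusters 1 and 2 (12493 and 12560 genes) 7% and 42%, and 2% and 39%. Cluster 4 gave 4% and 33% against smooth muscle-like cells (13298 genes), and 3% and 21% against pericyte-like cells (10834 genes). The female against the males gave 16% and 44% with 10 false calls in cluster 8 (14625 genes), and 18% and 47% with 7 false calls in fibroblast-like cells (18583 genes). With nothing changed, subcluster 2 and the sexes in fibroblast-like cells made 1 call each, and the other tests none. The simulated groups were fixed in advance, with no clustering step, no mouse effect and no correlation between genes. Calls that arise from forming classes on the same cells are therefore not covered. In the simulation of smooth muscle-like against pericyte-like cells, a list of 25 genes that all changed by 2 gave a camera p = 3.293e-13 with the preset and p = 0.168 with an estimated correlation.

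The alternatives were DESeq2 1.42.0 (size factors within edgeR, and its own Wald test), no filter on low counts, no mouse block, each mouse left out, the stricter cell filter, Leiden resolutions 0.5 and 2, the fixed lists kept among the clustering genes, no Scrublet calls, and each cell thinned to 50000 counts. Gene positions are those of GENCODE M21 on GRCm38. The 11 cells of the 4 mice with few cells entered the clustering but no test. Reads of the GFP and dsRed transgenes were not used here.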

Results

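Smooth muscle cells of the mouse heart and the cell types around them were profiled one cell at a time. Read counts were obtained for 1307 cells of 8 adult mice, each cell sequenced on its own with Smart-Seq2, a full-length cDNA method. Most cells came from 4 animals. Double-reporter mice, which carry green fluorescent protein under the control of Acta2 (smooth muscle alpha-actin) and red fluorescent protein under the control of Cspg4 (the NG2 proteoglycan of mural cells), gave 368, 245 and 336 cells for mice 1, 2 and 3. Mouse 1 of the inbred strain C57BL/6 gave 347 cells. The other 11 cells came from 4 mice with 1 to 4 cells each and entered no test. The design text calls the animals male and 8 to 30 weeks old, whereas the labels call double-reporter mouse 3 female. Median depth was 340988, 220866 and 208888 counts per cell in double-reporter mice 1, 2 and 3, and 307957 in C57BL/6 mouse 1.

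The first question was which cell types the sorted cells held. Smooth muscle-like cells carried contractile transcripts: Acta2 averaged 6715 CPM ± 1409 (SD, n = 3 double-reporter mice), Myh11, the smooth muscle myosin heavy chain, 3501 CPM ± 368, and Cnn1, the actin-binding calponin, 1093 CPM ± 447. Pericyte-like cells, the mural cells of capillaries, carried the potassium channel subunits Kcnj8 (4145 CPM ± 382) and Abcc9 (4164 CPM ± 1196), against 49.0 and 98.3 CPM in smooth muscle-like cells. Fibroblast-like cells were marked by Dcn, a collagen-binding proteoglycan (6094 CPM ± 1193). Cspg4 itself averaged 584 CPM ± 108 in smooth muscle-like, 1332 ± 229 in pericyte-like and 89.2 in fibroblast-like cells. These genes were used to name the classes and are not counted as results.

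Class shares differed between the sorted plates. Smooth muscle-like cells made up 33.7% of the cells of double-reporter mouse 1 (95% interval 28.9 to 38.8), 31.4% in mouse 2 (25.7 to 37.6) and 6.85% in mouse 3 (4.39 to 10.1), against 3 of 347 cells in C57BL/6 mouse 1 (0.865%, 0.179 to 2.51). Pericyte-like cells made up 13.3%, 5.31% and 2.68% of the double-reporter mice and 0.288% of the C57BL/6 mouse. Fibroblast-like shares were 20.4%, 37.6% and 49.4%, mostly of cluster 7 in mice 1 and 2 (70 of 75 and 64 of 92 cells) and of cluster 5 in mouse 3 (113 of 166 cells). Endothelial-like cells, which line vessels, were 70.3% of C57BL/6 mouse 1 (65.2 to 75.1) and at most 0.893% of each double-reporter mouse. Endocardial-like cells, the lining of the heart chambers, were 18.4% of that C57BL/6 mouse and 0 of 336 cells of double-reporter mouse 3, which allows a share of up to 0.893%. Schwann-like cells, the glia of peripheral nerves, were the class seen at 4.61% to 9.24% in all 4 animals. Macrophage-like cells reached 8.63% in double-reporter mouse 3. Between 17.96% and 26.2% of the cells of the double-reporter mice fell in 2 clusters left unnamed: cluster 4, with smooth muscle and pericyte markers (77, 20 and 5 cells), and cluster 0, with fibroblast and mesothelial markers (2, 24 and 83 cells). The sort gate sets such shares and is not stated, so they describe the plates and not the heart, and the intervals cover counting error only.

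**Figure D1:**
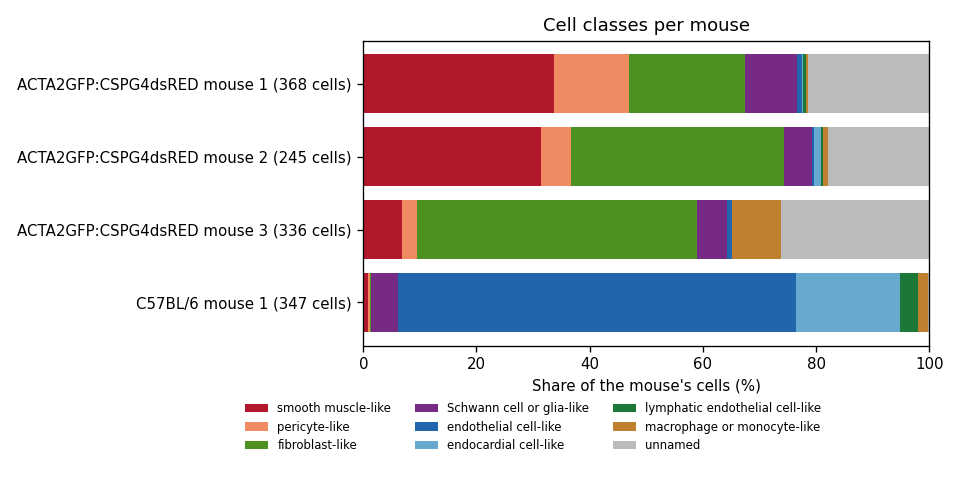
Share of each class among the sorted cells of the 4 mice with many cells (percent of the mouse's cells, x axis), stacked to 100% with 1 bar per mouse. Smooth muscle-like cells take 33.7%, 31.4% and 6.85% of double-reporter mice 1, 2 and 3, and endothelial-like cells 70.3% of C57BL/6 mouse 1.

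Smooth muscle-like and pericyte-like cells, both mural cells, were compared within the 2 mice with at least 10 cells of each (124 and 49 cells in mouse 1, 77 and 13 in mouse 2). Smooth muscle-like cells had more of the contractile genes beyond those used for naming. Actg2, the enteric smooth muscle actin, stood at 688 CPM ± 161 (SD, n = 2) against 6.19 in pericyte-like cells, and Ldb3, a Z-disc protein gene, at 314 ± 60.9 against 1.68. Eln, which encodes elastin, stood at 540 CPM ± 61.1 against 5.98, and Myocd, the transcriptional coactivator of contractile genes, at 496 ± 59.8 against 3.83. Actg2 and Eln were uneven within the smooth muscle-like class, with far less in its subcluster 0, as given below. Pericyte-like cells had more Lamb1, a laminin chain (378 CPM ± 180 against 1.29), more Hic1, a transcriptional repressor (319 ± 106 against 3.90), and more Ednrb, the endothelin receptor type B (482 ± 257 against 17.6). Of 14392 genes tested, 283 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 171 higher and 112 lower in smooth muscle-like cells, all in the same direction in both mice. Of these, 188 had neither entered the clustering nor served in naming. Without the mouse block the count was 96, and the fit has 1 residual degree of freedom.

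By list, 14 of 22 measured contractile genes were higher in smooth muscle-like cells and 1 was lower (17 and 1 when adjusted over the list alone). Actg2 changed by 6.81 on the log2 scale (SE 0.656, edgeR adjusted p = 0.0018) and Ldb3 by 7.43 (edgeR adjusted p = 0.0074). The member that went the other way was Itga7, an integrin that binds laminin, at 447 against 1215 CPM (log2 change -1.43, edgeR adjusted p = 0.0461). The list as a whole was shifted up in camera (adjusted p = 7.47e-13), with adjusted p = 0.539 with an estimated correlation. In fry, taken in a common direction, it had an adjusted p of 0.128. No list passed 0.05 in that test, and the lowest fry adjusted p was 0.0656, for basement membrane and interferon genes. With either direction allowed, fry gave an adjusted p of 0.0177 for the basement membrane, elastic fibre and growth factor lists. It gave 0.0257 for fibrillar collagen, 0.0308 for Notch and 0.0701 for contractile genes. Elastic fibre genes followed with 8 higher and 1 lower of 17 (9 and 2 adjusted over the list alone; camera adjusted p = 1.47e-05, and adjusted p = 0.539 with an estimated correlation). Among them Eln changed by 6.46 (SE 0.493, edgeR adjusted p = 0.000553) and Mfap4, a microfibril-associated glycoprotein, stood at 779 against 11.7 CPM, whereas Ltbp4, a latent TGF-beta binding protein, was lower at 384 against 1569 CPM. With at least 4 cells per sum, the median change of the elastic fibre list was 3.83 and 4.18 in mice 1 and 2. In mouse 3, with 9 pericyte-like cells, it was 1.10. Fibroblast naming markers were divided. Over 3 mice Dcn averaged 526 CPM in smooth muscle-like and 233 in pericyte-like cells, and Mfap5, a member of this list, 153 and 17.1. The means of Lum, Pdgfra and Pi16 were also higher in smooth muscle-like cells. Those of Col1a1 (389 against 421 CPM), Col1a2, Col3a1, Dpt and Tcf21 (23.2 against 95.7) were lower. Of 25 ion channel and calcium genes 3 were higher and none lower, the same when adjusted over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.539 with an estimated correlation). These included Kcnab1, a potassium channel beta subunit (407 against 5.93 CPM), and Cav1, the caveolar coat protein (1710 ± 278 against 197 CPM).

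Lists of matrix and receptor genes were divided between the classes. In the basement membrane list 3 of 20 genes were higher in smooth muscle-like cells and 4 lower (5 and 8 adjusted over the list alone). Npnt, an integrin ligand (251 against 1.43 CPM), and the laminin chain Lama5 were higher. Smooth muscle-like subcluster 0 had far less Npnt than the other smooth muscle-like cells, as given below. Lamb1 (log2 change -8.11, SE 0.601, edgeR adjusted p = 0.000492) and Nid1, which links laminin to collagen IV (62.2 against 831 CPM), were lower. The list's median change was -0.99, its mean 0.29, and camera placed it down (adjusted p = 0.0186, and adjusted p = 0.539 with an estimated correlation). Of 20 fibrillar collagen and proteoglycan genes 3 were higher and 3 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.687). The proteoglycans Ogn (614 against 27.9 CPM) and Lum (354 against 18.6), a fibroblast naming marker, were higher, and the collagen VI chains Col6a1 (142 against 1539) and Col6a2 (182 against 1053) lower. Of 27 vasoactive receptor genes 1 was higher and 4 lower (4 and 7 adjusted over the list alone). Ramp1, a subunit of the CGRP receptor, stood at 248 against 2.82 CPM, and Agtr1a, the angiotensin II receptor, at 5.19 against 171 CPM, although in mouse 2 only 2 of 13 pericyte-like cells held Agtr1a counts. That list had a median change of 0.49 and a mean of 1.38, while camera placed it down (adjusted p = 0.607). Over all tested genes the median change was 0.497. Leaving naming markers of every class out of the lists, a choice made after seeing the data, took 1 call each from the elastic fibre (Mfap5), fibrillar collagen (Lum), vasoactive (Rgs5) and growth factor (Pdgfrb) lists.

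Of the 14 measured genes of the fixed Notch list edgeR called only Nrip2, at 804 against 15.99 CPM. Adjusted over the list alone 1 was higher and 4 lower (camera adjusted p = 0.0876). Nrip2 counts here as a member of that list, and its place in the Notch pathway was not tested. With the naming marker Notch3 left out, DESeq2 called 3 of 13. With smooth muscle-like cluster 9 only, for smooth muscle-like versus pericyte-like cells, Nrip2 had a log2 change of -0.81. Of 27 mural transcription factors Myocd was higher (log2 change 7.09, SE 0.641, edgeR adjusted p = 0.0013), and Hic1 and the T-box factor Tbx20 were lower (1 and 4 adjusted over the list alone; camera placed the list down with adjusted p = 0.407, its median change was 0.13 and its mean 0.66). Of 25 growth factor signalling genes Eng and Nrp1, co-receptors for TGF-beta and VEGF, were among the 3 called lower, with log2 changes of -2.38 and -2.24 (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.738). No gene of that list was called higher by edgeR over all genes. Of 23 interferon and inflammatory genes 2 were lower, the antigen-presentation genes H2-D1 (313 against 1364 CPM) and B2m (485 against 1528), and 9 were lower adjusted over the list alone (camera adjusted p = 1.43e-09, and adjusted p = 0.539 with an estimated correlation). In mouse 2, 3 of 13 pericyte-like and 0 of 77 smooth muscle-like cells held over 500 CPM of 8 endothelial markers, and in mouse 1 2 of 49 and 7 of 124. Without such cells 475 genes were called. Of 25 immediate early genes, which respond to dissociation, 4 were higher, among them Nr4a1 (869 against 147 CPM) and Zfp36 (917 against 209), and 8 adjusted over the list alone (camera adjusted p = 0.0251, and adjusted p = 0.589 with an estimated correlation). For glycolysis edgeR called 0 of 18 genes, also adjusted over the list alone, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.232). DESeq2 called 1, Pfkm, a phosphofructokinase gene at 133 against 5.77 CPM (edgeR adjusted p = 0.109). Of 25 oxidative phosphorylation genes Ndufa4, a cytochrome oxidase subunit, was called, at 145 against 5.20 CPM (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.607).

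The largest changes outside the clustering genes included Smim5, a small membrane protein gene (5012 against 1 counts over both mice, a ratio of 1552 with a counting interval from 278.6 to 61301.8), and Plin4, a lipid droplet coat gene (162 against 0.291 CPM), both higher in smooth muscle-like cells. Nuak2, a kinase gene, was higher in pericyte-like cells (967 against 3 counts, a ratio of 1041 with an interval from 356.2 to 5047.5), yet 1 cell gave 99.5% of its pericyte-like counts in mouse 2. Genes that helped to form the clusters, such as Fmo2, Sost and Ccn3 on the smooth muscle side and Vipr1, Sele and Gpr182 on the pericyte side, define the classes. So does Cd4, with 0 counts in smooth muscle-like cells, which puts it at least 533.9-fold higher in pericyte-like cells against a floor of 3 counts over the group.

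Smooth muscle-like cells were next compared with fibroblast-like cells in all 3 double-reporter mice (124 and 75, 77 and 92, and 23 and 166 cells). Casq2, the calcium store protein calsequestrin, averaged 1023 CPM ± 525 (SD, n = 3) against 1.73 in fibroblast-like cells, Actg2 511 ± 285 against 2.60, and Myocd 527 ± 92.5 against 11.02. Fibroblast-like cells had more of the matrix genes Fbln2 (814 CPM ± 592 against 32.1) and Fmod, which encodes fibromodulin (2191 ± 1640 against 82.4), and of Bmp4, a secreted growth factor (196 ± 69.0 against 3.74). Of 15813 genes tested with edgeR, 856 passed, 408 higher and 448 lower in smooth muscle-like cells, all in the same direction in the 3 mice. Of these, 650 had neither entered the clustering nor served in naming. Leaving out mouse 1 left 414 calls and leaving out mouse 2 left 208. Fibroblast-like cells of mice 1 and 2 were mostly of cluster 7 and those of mouse 3 mostly of cluster 5. Cluster 7 had 5 of 10 fibroblast naming markers raised and cluster 5 had 9. Pdgfra stood at 118 CPM in cluster 7 against 538 in cluster 5, and Tcf21 at 35.0 against 305. The 10 leading genes of cluster 7 included Wif1, Chad, Prg4 and Fmod. Genes that mark cluster 7 may therefore not hold for all fibroblast-like cells.

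Every one of the 18 called contractile genes, of 22 measured, was higher (21 adjusted over the list alone; camera adjusted p = 1.33e-47, and adjusted p = 0.0524 with an estimated correlation). Ldb3 changed by 7.76 (SE 0.490, edgeR adjusted p = 0.00496). In fry, taken in a common direction, the contractile list had an adjusted p of 0.00835. Only the basement membrane (fry adjusted p = 0.509) and interferon (fry adjusted p = 0.0514) lists stayed above 0.05. In the ion channel and calcium list 12 of 28 were higher and none lower (17 and 1 adjusted over the list alone; camera adjusted p = 2.21e-20, and adjusted p = 0.115 with an estimated correlation). Casq2 changed by 9.15 (SE 0.467, edgeR adjusted p = 0.00441) and Cacna1h, a T-type calcium channel, by 8.95 (SE 0.385, edgeR adjusted p = 0.00359) at 174 ± 192 CPM. Of 30 vasoactive genes 8 were higher and 3 lower (16 and 5 adjusted over the list alone; camera adjusted p = 1.83e-07, and adjusted p = 0.115 with an estimated correlation). Rgs4, a regulator of G-protein signalling, stood at 1381 ± 355 against 18.6 CPM and S1pr3, a sphingosine phosphate receptor, at 699.8 ± 219 against 47.5, whereas Lpar1, a lysophosphatidic acid receptor, stood at 3.75 against 276 and the nucleotide receptor P2ry1 at 0.221 against 31.98. Without naming markers of every class the vasoactive and Notch lists each lost 1 call (Rgs4 and Notch3). S1pr3 had a log2 change of -3.41 with smooth muscle-like cluster 9 only, at least 4 cells.

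In the fibrillar collagen and elastic fibre lists more genes were lower than higher. Of 15 fibrillar collagen and proteoglycan genes 11 were lower in smooth muscle-like cells and none higher (12 and 0 adjusted over the list alone; camera adjusted p = 4.96e-15, and adjusted p = 0.115 with an estimated correlation), with Fmod changed by -4.68 (SE 0.747, edgeR adjusted p = 0.0333) and Vcan, the proteoglycan versican, at 13.8 against 210.4 CPM. Of 17 elastic fibre genes 5 were lower and 1 higher (11 and 2 adjusted over the list alone; camera adjusted p = 1.83e-07, and adjusted p = 0.221 with an estimated correlation). Fbln2 and Ltbp2 (9.62 against 221 CPM) were lower and Adamtsl1 higher (178 ± 10.9 against 13.1). For Adamtsl1 the log2 change was -2.92 with smooth muscle-like cluster 9 only, at least 4 cells. The basement membrane list split into 4 higher and 2 lower of 20 (5 and 5 adjusted over the list alone; camera adjusted p = 0.666), with Col18a1 (335 ± 118 against 34.5 CPM) and Npnt higher, and Lamb1 (4.35 against 386) and Lama2 (52.5 against 414) lower. Npnt had a log2 change of -0.70 with smooth muscle-like cluster 8 only. Of 25 interferon and inflammatory genes 5 were lower (9 adjusted over the list alone; camera adjusted p = 1.22e-05, and adjusted p = 0.221 with an estimated correlation), among them the adhesion gene Icam1 (3.02 against 131 CPM) and the cytokine gene Il33 (13.4 against 149).

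In the fixed Notch list 5 of 14 genes were higher. Adjusted over the list alone 7 were higher and 1 lower (camera adjusted p = 1.89e-08, and adjusted p = 0.197 with an estimated correlation). Among them the list member Nrip2 stood at 998 ± 433 against 3.18 CPM and the Notch-regulated gene Nrarp at 159 ± 93.5 against 0.51. Of 26 transcription factors 6 were higher and 1 lower (12 and 3 adjusted over the list alone; camera adjusted p = 0.00042, and adjusted p = 0.197 with an estimated correlation). Tbx2 stood at 186 ± 124 against 2.74 CPM and Tbx20 at 33.0 against 449 ± 178. Tbx2 reversed with smooth muscle-like cluster 9 only, at least 4 cells (log2 change -2.23). Of 25 growth factor signalling genes 1 was higher and 4 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.01, and adjusted p = 0.221 with an estimated correlation). Tek, the angiopoietin receptor, stood at 0.362 against 72.4 CPM, and Pdgfb, the one called higher, at 24.96 against 0.0601 CPM, with 99.4% of the smooth muscle-like counts of mouse 3 from 1 cell. Glycolysis gave 2 of 18 higher and none lower (9 and 0 adjusted over the list alone; camera adjusted p = 1.81e-05, and adjusted p = 0.221 with an estimated correlation), including the glucose transporter Slc2a1 (139 ± 37.7 against 21.6 CPM) and Gpi1 (689 ± 42.3 against 269.9). Oxidative phosphorylation gave 5 of 25 higher and none lower (18 and 0 adjusted over the list alone; camera adjusted p = 1.19e-09, and adjusted p = 0.221 with an estimated correlation), including the ATP synthase subunit Atp5b (2333 ± 523 against 823 CPM) and Cox8a (513 ± 214 against 179). Of 25 immediate early genes Atf3 and Btg2 were higher (3 adjusted over the list alone; camera adjusted p = 0.13, with a median change of -0.07 and a mean of 0.15). With cluster 9 only, Atf3 had a log2 change of -0.74. The largest changes outside the clustering genes were those of the cadherin Cdh6 (118 ± 7.30 against 0.149 CPM) and the actin-binding Xirp1 (108 ± 53.0 against 0.132) among higher genes. Among lower genes they were those of Lgr5, an R-spondin receptor (0.0881 against 63.9), and the prostaglandin receptor Ptgfr (0.258 against 126.5). Lgr5 was among the 10 leading genes of a cluster of 80 cells at Leiden resolution 2, all of them from cluster 7.

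**Figure D2:**
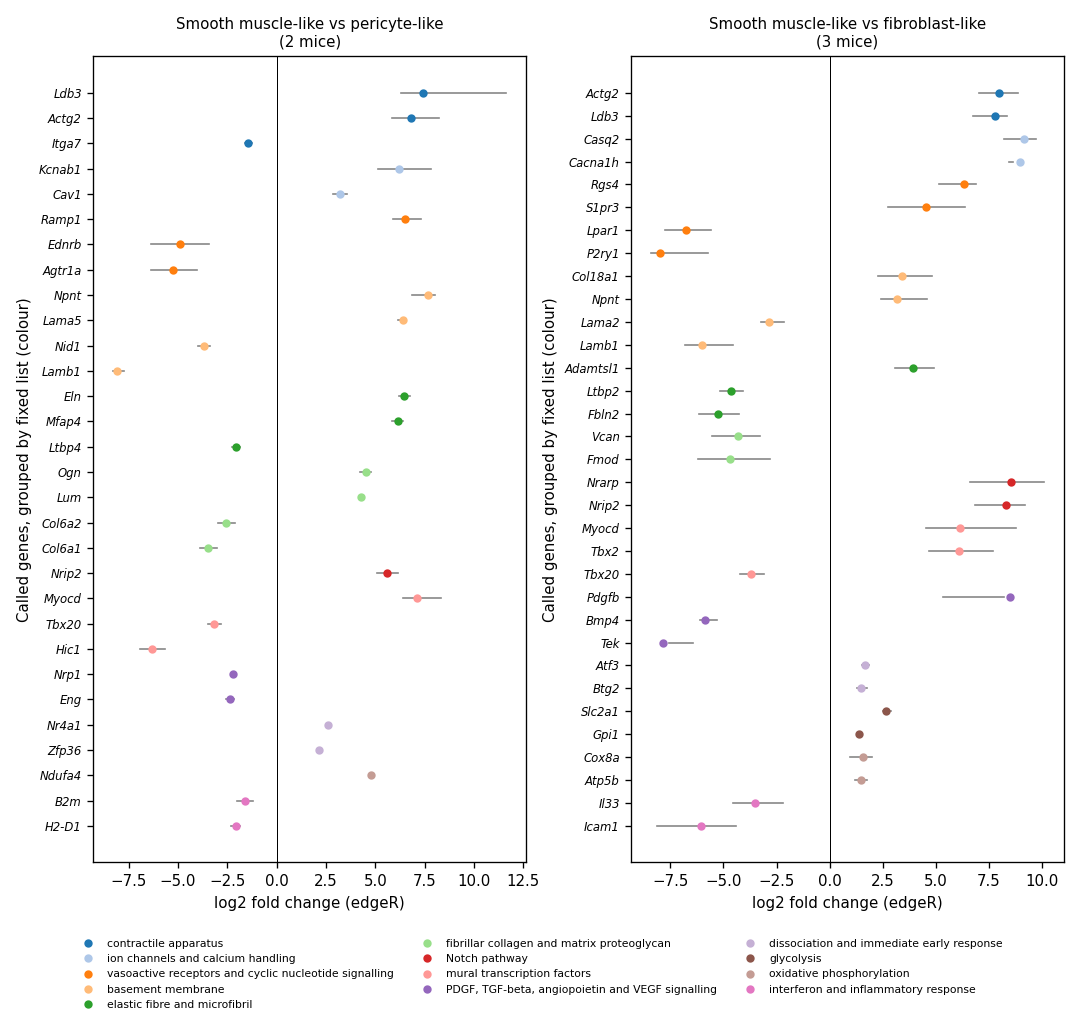
Log2 changes from edgeR (x axis) of fixed-list genes that passed an adjusted p of 0.05, coloured by list, for smooth muscle-like against pericyte-like cells (2 mice) and against fibroblast-like cells (3 mice). Grey lines span the lowest to highest change of single mice; Eln stands at 6.46 in the first comparison and Casq2 at 9.15 in the second.

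Pericyte-like cells had at least 10 cells in 2 of the mice with fibroblast-like cells, so the planned comparison is given as values. Of 6525 genes with an average log2 CPM of at least 5, 263 were at least 4-fold higher in pericyte-like sums in both mice and 423 at least 4-fold lower. For pericyte-like versus fibroblast-like cells this total of 686 became 1872 without mouse 1 and 1027 without mouse 2, where 1 mouse alone decides. Casq2 stood at 969 and 1323 CPM in the pericyte-like cells of mice 1 and 2 against 1.93 and 0.971 in fibroblast-like cells, and Ednrb at 309 and 656 against 0.848 and 0.283. Itga7 stood at 1104 and 1344 against 10.7 and 11.6 CPM. On the fibroblast side Fbln1, a fibulin of elastic fibres, stood at 5.47 and 7.11 CPM in pericyte-like against 2221 and 2557 in fibroblast-like cells, and Vcan at 0.533 and 1.29 against 218 and 154.

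With 9 pericyte-like cells of mouse 3 admitted, a test over 3 mice, added after seeing the data, called 391 of 14797 genes in edgeR, 165 higher and 226 lower in pericyte-like cells. Over all tested genes the median change was -0.696. Itga7 changed by 6.44 (SE 0.418, edgeR adjusted p = 0.000781), Casq2 by 9.57 (SE 0.492, edgeR adjusted p = 0.000539) and Ednrb by 8.58 (SE 1.05, edgeR adjusted p = 0.00524). Contractile genes gave 5 of 30 higher (10 and 1 lower adjusted over the list alone; camera adjusted p = 9.87e-09, and adjusted p = 0.212 with an estimated correlation). Ion channel genes gave 4 of 26 (5 and 1; adjusted p = 4.79e-07, and adjusted p = 0.1 with an estimated correlation), and vasoactive genes gave 7 higher and 1 lower of 26 (9 and 4; adjusted p = 8.85e-06, and adjusted p = 0.192 with an estimated correlation). Elastic fibre genes gave 7 of 17 lower (10 adjusted over the list alone; camera adjusted p = 9.87e-09, and adjusted p = 0.1 with an estimated correlation), with Ltbp2 at 0.519 against 222 CPM. Fibrillar collagen genes gave 7 lower and 1 higher of 15 (10 and 1; adjusted p = 4.79e-07, and adjusted p = 0.1 with an estimated correlation), the higher one being Fn1, fibronectin, at 692 ± 86.0 against 209 CPM. Notch genes gave 4 of 15 higher (8 and 1 adjusted over the list alone; camera adjusted p = 9.87e-09, and adjusted p = 0.1 with an estimated correlation), among them Notch4 at 79.5 ± 95.4 against 0.187 CPM. The Notch4 mean rests on mouse 3, with 45.9, 6.47 and 178 CPM in mice 1, 2 and 3, and on 2 of its 9 cells. Transcription factors gave 3 of 26 higher (8 and 4; camera adjusted p = 0.0002, and adjusted p = 0.131 with an estimated correlation), with Foxs1 at 428 against 35.6 CPM. Basement membrane genes gave 3 of 20 higher (3 and 2; camera placed the list up with adjusted p = 0.0758, its median change was 0.12 and its mean -0.65), with Itga1 at 652 ± 136 against 64.4 CPM. Growth factor genes gave 1 higher and 1 lower of 24 (1 and 5; adjusted p = 0.127), immediate early genes 3 of 25 lower (0 and 8; adjusted p = 0.017, and adjusted p = 0.508 with an estimated correlation), glycolysis 1 of 17 higher (2 and 0; adjusted p = 0.00147, and adjusted p = 0.255 with an estimated correlation) and oxidative phosphorylation 2 of 25 higher (2 and 1; adjusted p = 1.85e-06, and adjusted p = 0.212 with an estimated correlation). Of 24 interferon and inflammatory genes edgeR called 0, also adjusted over the list alone, with 6 at an unadjusted p under 0.05 and 3 called by DESeq2 (camera adjusted p = 0.0652; the median change was 0.40 and the mean -0.26). Without naming markers of every class the contractile, vasoactive, Notch and growth factor lists each lost 1 call of a higher gene (Mylk, Rgs5, Notch3 and Pdgfrb). Camera then placed the growth factor list down (adjusted p = 0.0208, and adjusted p = 0.327 with an estimated correlation). Without the mouse block 995 genes were called, and without mouse 1 220.

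No mouse had 10 cells of both the smooth muscle-like and the endothelial-like class. The double-reporter mice's smooth muscle-like sums are therefore set beside the 244 endothelial-like cells of C57BL/6 mouse 1 without a test, and class, strain and plate cannot be told apart. Myl9, a myosin light chain, stood at 4161 CPM ± 838 (SD, n = 3) against 163 in endothelial-like cells, Gucy1a1, a subunit of the nitric oxide receptor, at 1977 ± 388 against 108, and Kcnmb1, a potassium channel subunit, at 340 ± 45.7 against 9.27. Endothelial-like cells had the Notch ligand gene Dll4 at 452 CPM against 0.017, Tek at 528 against 0.345, and Eng at 2504 against 102 ± 75.5. At least 4-fold and in the same direction in all 3 mice, 15 of 22 contractile genes, 14 of 20 fibrillar collagen genes and 10 of 29 transcription factors were higher in smooth muscle-like sums, with none lower. The ion channel list gave 10 higher and 1 lower of 29, the elastic fibre list 7 and 1 of 18, the vasoactive list 11 and 3 of 35, the Notch list 5 and 4 of 16 and the basement membrane list 2 and 2 of 20. The interferon list gave 9 lower and none higher of 25 and the growth factor list 6 lower and 1 higher of 24. Of the immediate early genes 1 was lower, and no glycolysis or oxidative phosphorylation gene differed by that much. Endothelial-like cells of this mouse also held heart muscle transcripts, with Mb at 236 CPM.

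Within the smooth muscle-like class, clustering at resolution 0.5 gave 3 subclusters, and subcluster 0 alone had at least 10 cells in 3 mice (35, 20 and 15 cells, against 89, 57 and 8 other smooth muscle-like cells). It had more Casq2, at 2130 CPM ± 426 (SD, n = 3) against 376 in the other smooth muscle-like cells. The mural naming markers Rgs5, a regulator of G-protein signalling (8745 ± 2190 against 1457), and Notch3 (1451 ± 270 against 340.1) were higher too and serve as class checks. It had less of the matrix genes Eln (25.8 against 514 CPM), Fbln5 (14.4 against 1084), Npnt (1.28 against 439) and Ogn (11.2 against 730.3), and less Actg2 (45.1 against 716 ± 202). Of 11898 genes edgeR called 40, 9 higher and 31 lower, of which 11 had neither entered the clustering nor served in naming. Without mouse 1 the count was 0 in edgeR, with 582 genes at an unadjusted p under 0.05 and 465 called by DESeq2. The fibroblast naming markers Col1a1 and Col3a1 were among the genes called. They averaged 54.2 and 108 CPM in cluster 8, which held all 71 cells of subcluster 0, against 1004 and 1483 in cluster 9. With naming markers of every class left out of the lists after seeing the data, 3 of 15 fibrillar collagen genes were lower (9 adjusted over the list alone; camera adjusted p = 6.66e-11, and adjusted p = 0.248 with an estimated correlation), as were 3 of 16 elastic fibre genes (7 adjusted over the list alone; camera adjusted p = 2.26e-09, and adjusted p = 0.248 with an estimated correlation). In the ion channel list 1 of 24 was higher, Casq2 (5 adjusted over the list alone; camera adjusted p = 4.96e-05, and adjusted p = 0.271 with an estimated correlation). In the vasoactive list edgeR called 0 of 21 genes, with 6 at an unadjusted p under 0.05 and 6 called by DESeq2 (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00139, and adjusted p = 0.432 with an estimated correlation). The Notch list gave 0 of 11 in edgeR, with 3 at an unadjusted p under 0.05 and 3 called by DESeq2 (3 adjusted over the list alone; camera adjusted p = 0.000912, and adjusted p = 0.271 with an estimated correlation). Subcluster 1 (52, 18 and 4 cells, 72 of 75 from cluster 9), tested after seeing the data, had more Eln (1009 ± 662 against 62.0 CPM), Fbln5 (2136 ± 1010 against 52.2) and Col1a1 (1016 ± 467 against 81.4) and less Rgs5 (255 against 5741 ± 1660) than the rest, with 38 genes called in edgeR, of which 8 higher and 1 lower had neither entered the clustering nor served in naming. The means of some fibroblast naming markers went the same way, without a call: Dcn at 1088 against 248 CPM, Lum at 946 against 45.0 and Mfap5 at 456 against 16.2. Col1a1 is such a marker too. Whether fibroblast RNA adds to this subcluster was not tested.

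The sexes were compared within smooth muscle-like cells as the female mouse against both males. The female arm has 1 mouse, which is assumed to vary like the males, and the fit has 1 residual degree of freedom. Xist, the RNA that silences 1 X chromosome in females, stood at 1168 CPM in the female and at 0.026 and 0 in the males (log2 change 15.65, edgeR adjusted p = 0.00735) and was the only gene called of 16114, with 3904 at an unadjusted p under 0.05. The Y-linked genes Ddx3y (130.4 and 106 CPM in the males) and Eif2s3y (106 and 79.6) had 0 counts in the female. Acta2 stood at 5178, 7944 and 7023 CPM and Cspg4 at 463, 617 and 672 in mice 1, 2 and 3, with no call for either. For female versus male mice within a class the DESeq2 Wald test called 2522 genes, and edgeR called 429 on cluster 8 alone, which held 75 of 124, 57 of 77 and 19 of 23 of the cells. In fibroblast-like cells, tested after seeing the data, edgeR called 4 of 18583 genes, while a simulation of this test with 200 genes changed made 7 false calls (9.72% of its calls), and 1 call with nothing changed. Reads counted for Tsix were higher in the female at 284 against 0 CPM (edgeR adjusted p = 0.0386). Tsix overlaps Xist on the other strand, and as the strand setting was not given, they cannot be told from reads of Xist. In the female Ddx3y, Eif2s3y and Coch, an extracellular matrix gene, were lower. The female's fibroblast-like cells are mostly of cluster 5 and the males' of cluster 7, and Coch stood at 0.19 CPM in cluster 5 and at 146 in cluster 7. Sex, mouse, plate and, in fibroblast-like cells, the mix of clusters cannot be separated. Pericyte-like cells of the female (9) were too few for this test.

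C57BL/6 mouse 1 had 3 smooth muscle-like and 1 pericyte-like cell, too few for the planned comparison of strains. The 1 class with at least 10 cells in all 4 mice was Schwann-like (34, 12, 18 and 16 cells), and its test was added after seeing the data. The C57BL/6 arm has 1 mouse, which is assumed to vary like the double-reporter mice. Of 14214 genes edgeR called 41, of which 40 were lower in the double-reporter mice, while a simulation of this test with 200 genes changed made 7 false calls (18.4% of its calls), and none with nothing changed. For double reporter versus C57BL/6 mice within Schwann-like cells the count was 158 without mouse 1, 68 without mouse 3, 144 with no low-count filter and 605 with the DESeq2 Wald test. Of the 10 endothelial naming markers, 7 were among these 40. Cav1 stood at 2.77, 5.32 and 4.93 CPM in the double-reporter mice against 1894 in the C57BL/6 mouse, and the fatty acid binding gene Fabp4 at 3.32, 15.3 and 9.10 against 1400. The sum of 8 endothelial markers had a median of 3660 CPM in the 16 Schwann-like cells of the C57BL/6 mouse and of 4.19 in the 64 of the double-reporter mice. Cells of other classes of the C57BL/6 mouse held these markers too, as given below. Galnt6, a glycosyltransferase gene, was the 1 gene higher, at 160, 246 and 162 CPM against 0 (edgeR adjusted p = 0.0201). Cspg4 stood at 514, 519 and 373 CPM in double-reporter mice 1, 2 and 3 against 77.9, and Acta2 at 78.4, 61.0 and 12.4 against 369. Neither was called, in a test that recovered 3% of simulated log2 changes of 2.

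**Figure D3:**
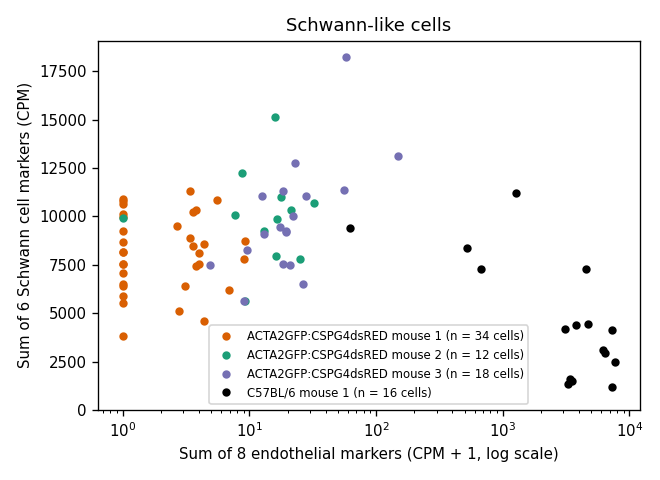
Single Schwann-like cells of the 4 mice by the sum of 8 endothelial markers (x axis, CPM + 1, log scale) and the sum of 6 Schwann cell markers (y axis, CPM), 1 point per cell. The 16 cells of C57BL/6 mouse 1 have an endothelial sum from 61.8 to 7707 CPM with a median of 3660, against a median of 4.19 in the 64 cells of the double-reporter mice.

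Positions on GRCm38 of the main genes named, from the annotation, are as follows. Eln (ENSMUSG00000029675) lies on chromosome 5 from 134702593 to 134747323, Myocd (ENSMUSG00000020542) on chromosome 11 from 65176561 to 65269989, and Ldb3 (ENSMUSG00000021798) on chromosome 14 from 34526603 to 34588682. Casq2 (ENSMUSG00000027861) and Npnt (ENSMUSG00000040998) both lie on chromosome 3, from 102086415 to 102146514 and from 132881745 to 132950291. Lamb1 lies on chromosome 12 from 31265234 to 31329644, Itga7 on chromosome 10 from 128933818 to 128958282, and Ednrb on chromosome 14 from 103814625 to 103844402. Counts were made over whole genes, so they do not separate transcripts or exons.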

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

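The tests on the Schwann-like cells and the splits of the sums were written after the results were seen. Median changes of gene lists in the female mouse, double-reporter mouse 3, had the opposite sign to those of both males in 5 cases. Between smooth muscle-like and pericyte-like cells the fibrillar collagen list had a median log2 change of -0.003 in the female and of 0.421 and 1.196 in the males. The Notch list had 0.874 against -0.204 and -0.493, and the glycolysis list -0.23 against 0.289 and 0.397. Between pericyte-like and fibroblast-like cells the basement membrane list had -0.907 against 0.802 and 0.21, and the interferon list -0.998 against 0.718 and 0.801. Signs ignore that the median change over all tested genes was 0.505 in the first comparison and -0.696 in the second. The glycolysis list lay below 0.505 in the female and both males, and the fibrillar collagen list in the female and 1 male. The Notch, basement membrane and interferon cases kept opposite sides of these medians. Wider gaps without a change of sign in both males were not singled out, such as -2.956 against -0.959 and -1.031 for the interferon list between smooth muscle-like and fibroblast-like cells. The female's pericyte-like values rest on 9 cells. These differences were not tested, and sex, mouse and plate cannot be separated in 1 female.

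The labels give the 3 cells of the ACTA2GFP mouse both sexes, 1 cell female and 2 male. The cell labelled female held 7 counts of Y-linked genes, 3 of Ddx3y (35.3 CPM) and 4 of Eif2s3y, and 0 counts of Xist, the RNA of the silenced X chromosome. Xist was found in 336 of 336 cells of double-reporter mouse 3, at 878 CPM. Whether the label of the single cell holds was not tested.

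Schwann-like cells of C57BL/6 mouse 1 carried endothelial transcripts such as Cav1 and Fabp4, and 3 explanations were weighed. They were not alone in this mouse. The sum of 8 endothelial markers was above the threshold of 500 CPM in 3 of 3 smooth muscle-like cells, the 1 pericyte-like and the 1 fibroblast-like cell. The 6 macrophage-like cells had a median of 930 CPM, against 20.5 in the 32 of the double-reporter mice. Free endothelial RNA spread evenly over the plate would give like amounts per cell, yet the highest cell had 124.7 times the endothelial marker sum of the lowest. An endothelial cell in the same well could give it, and so could free RNA spread unevenly, and these cannot be told apart. The endothelial and Schwann shares of the 15 cells above the threshold added up to a median of 0.988 (0.522 to 1.391 in single cells), but any mixture of the 2 RNAs gives a sum near 1. The endothelial share alone ran from 0.059 to 0.869. These 15 cells had a median of 5921 genes against 4055 in the double-reporter mice. Scrublet called 0 doublets in this mouse. A difference between strains could not be told, with 0 Schwann-like cells of another C57BL/6 mouse. Mouse and plate are the same here.

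Labels of the class sums were exchanged in all 10 splits of the 6 sums. For smooth muscle-like versus fibroblast-like cells 856 genes were called in the real split, for smooth muscle-like versus pericyte-like cells with at least 4 cells 198, and for pericyte-like versus fibroblast-like cells with at least 4 cells 391. Smooth muscle subclusters 0, 1 and 2 versus the rest gave 40, 38 and 2, and cluster 4 versus smooth muscle-like and versus pericyte-like cells 2 each. In each case 1 split of the 10, the real one, had as many genes called, and the highest other gave 0. Of the 10 splits 4 part the sums of every mouse, and the highest other among these also gave 0. A set of 10 splits of 6 sums cannot give a share under 0.05. The other splits leave the class difference in the residual spread, and the classes were formed from these same cells. The real split was therefore bound to come first, and no conclusion is drawn from it.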

How the results depend on the processing

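For smooth muscle-like versus pericyte-like cells, 283 genes were called. The count was 458 with DESeq2 size factors, 1142 with the DESeq2 Wald test, 648 with no low-count filter and 96 with no replicate block. With smooth muscle-like cluster 8 only it was 92, with cluster 9 only 479, and without cells above 500 CPM of endothelial markers 475. Of the named genes Nrip2 reversed with cluster 9 only (-0.81). The other values of named genes gave 634 the same, 65 weaker, 5 stronger and 9 moved, all in the same direction. Leaving out a mouse left values of single genes without a test, and strict cells left 1 mouse and were not run. In gene lists, smooth muscle-like versus pericyte-like, camera with an estimated correlation gave an adjusted p of 0.539 for contractile apparatus, ion channels and calcium handling, basement membrane, elastic fibre and microfibril, and interferon and inflammatory response, and of 0.589 for dissociation and immediate early response; 72 other values stayed the same.

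For smooth muscle-like versus fibroblast-like cells, 856 genes were called, 2910 with the DESeq2 Wald test, 139 with cluster 9 only and at least 4 cells, and 208 to 1071 with a mouse left out (414 without mouse 1, 208 without mouse 2). Npnt reversed with cluster 8 only (-0.70), and S1pr3 (-3.41), Adamtsl1 (-2.92), Tbx2 (-2.23) and Atf3 (-0.74) with cluster 9 only. Of the other values of named genes 699 were the same and 71 weaker.

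For pericyte-like versus fibroblast-like cells, at least 4 cells per class and mouse, 391 genes were called, 2409 with the DESeq2 Wald test, 995 with no replicate block, 240 with strict cells and 220 to 531 with a mouse left out (220 without mouse 1). Of the named genes' values 507 were the same, 62 weaker and 5 stronger. For pericyte-like versus fibroblast-like cells by values, 686 genes became 1027 to 1872 with a mouse left out (1872 without mouse 1).

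For female versus male mice within a class, 1 gene was called, 2 with DESeq2 size factors, 2697 with no low-count filter, 2522 with the DESeq2 Wald test, 429 with cluster 8 only and 4 with fibroblast-like cells. For double reporter versus C57BL/6 mice within Schwann-like cells, 41 became 144 with no low-count filter, 605 with the DESeq2 Wald test and 48 to 158 with a mouse left out (158 without mouse 1, 68 without mouse 3). For smooth muscle subcluster 0 versus the other smooth muscle-like cells, 40 became 76 with no replicate block and 0 to 18 with a mouse left out (0 without mouse 1, 18 without mouse 2, 15 without mouse 3). Of class shares per mouse 160 stayed the same and 20 moved, among them smooth muscle-like in ACTA2GFP:CSPG4dsRED mouse 1 at Leiden resolution 2 (27.45%) and pericyte-like in ACTA2GFP:CSPG4dsRED mouse 2 with strict cells (2.74%). The cause was not tested.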

Other observations

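The tests on cluster 4 and the test for cardiomyocyte RNA behind Tnnt2 were written after the results were seen. Cluster 4, left unnamed, held 77, 20 and 5 cells of double-reporter mice 1, 2 and 3 with markers of both mural classes. Acta2 averaged 3405 CPM ± 833 (SD, n = 3), Rgs5 4083 ± 3030 and Vtn, a plasma adhesion protein gene that marks pericytes, 2172 ± 729. It also held fibroblast markers: Dcn averaged 1436 CPM ± 472 and Dpt, the dermatopontin gene, 602 ± 416, against 526 and 26.4 in smooth muscle-like, 233 and 34.6 in pericyte-like and 6094 and 1196 in fibroblast-like cells. In every mouse Zeb2, Angpt2 and Ccl19 stood at least 2-fold above the smooth muscle-like, pericyte-like and fibroblast-like classes, though edgeR called none of them against the smooth muscle-like or pericyte-like class; other classes were not compared. Zeb2, a transcriptional repressor, averaged 518 CPM ± 33.6 against 139 in smooth muscle-like, 190.3 in pericyte-like and 112.0 in fibroblast-like cells. Angpt2, an angiopoietin that acts on vessel stability, averaged 473 ± 104.0 CPM against 197.9 in smooth muscle-like cells, and Ccl19, a chemokine gene, 167.8 ± 47.8 against 8.86, 8.49 and 39.6. The chemokine gene Ccl11 (374 CPM) and Chrdl1, a BMP antagonist gene (649.9 CPM), helped to form the cluster. In tests added after seeing the data edgeR called 2 genes against smooth muscle-like cells and 2 against pericyte-like cells, among the latter S1pr3, lower in cluster 4 at 3.01 against 1493 CPM (edgeR adjusted p = 0.0219).

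A smooth muscle-like and a pericyte-like cell in the same well could give both sets of markers, but 23 genes outside the clustering genes were at least 2-fold above all 3 classes in every mouse, against at most 1 in 100 simulated sets of such pairs. Of the 5 cells of mouse 3, 1 had a melanocyte profile. Without it the count was again 23, against at most 1 in simulated pairs of these classes and at most 1 in pairs of a fibroblast-like with either mural cell. More RNA per well is another candidate explanation. Median counts were 1.03 times those of smooth muscle-like and 0.976 times those of pericyte-like cells in mouse 1, and 1.06 and 2.13 times in mouse 2, where the explanation needed 1.5 against both classes. Random simulated pairs of these classes did not account for the 23 genes. A mixture of 2 classes can hardly stand 2-fold above both, so a low count in such pairs was set in advance. The real cells were grouped by clustering and the simulated pairs were not. Clustering can also lift genes that vary with the clustering genes. Pairs picked by clustering, and pairs with other cells, such as those of cluster 0, were not simulated, so 2 cells in a well are not excluded. Read counts without molecular identifiers do not measure RNA per well, so the test of median counts cannot decide that question. No biological explanation was tested.

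Tnnt2, the cardiac troponin T gene, stood at 707 CPM in smooth muscle-like cluster 9, at 359 in endothelial-like cluster 1, at 323 in fibroblast-like cluster 10 and at 138 in smooth muscle-like cluster 8. Its median in cluster 9 was 489 CPM in mouse 1 (46 of 49 cells), 99.5 in mouse 2 (13 of 20) and 5.23 in mouse 3 (3 of 4), against 5.81, 0 and 11.99 in cluster 8. RNA from cardiomyocytes could carry it. In the 62 cells with counts, pooled over mice, the median sum of 6 other cardiomyocyte transcripts was 0.021 of the Tnnt2 median. Over all cluster 9 cells that sum had medians of 4.98, 15.6 and 8.87 CPM in mice 1, 2 and 3. It was far below Tnnt2 in mouse 1, less so in mouse 2 and not below it in mouse 3. The values thus speak against cardiomyocyte RNA mainly in mouse 1. An abundant transcript of a few cells could also carry Tnnt2, yet in mice 1 and 2 at most 33.9% of the counts came from 1 cell. In mouse 3, which that test did not cover, 1 of the 4 cells gave 97.3%. Cluster 10, with a median of 476 CPM in the 4 cells of mouse 1 and of 2.29 and 0 in mice 2 and 3, was not tested. No biological explanation was tested.

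A well of double-reporter mouse 3, placed in cluster 4, had the pigment genes Dct (8473 CPM), Pmel (4199) and Tyrp1 (2842) with Acta2 at 30.0 CPM and 0 counts of Rgs5, a melanocyte profile in 1 cell. Among the mice with few cells, an endothelial-like cell of C57BL/6 mouse 2 held Rgs5 at 22803 CPM, and an ACTA2GFP cell of cluster 4 held Acta2 at 2361 and Rgs5 at 8617 CPM. In these cells 3.24% to 11.12% of the counts were mitochondrial.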
